A study of Mus musculus with 112 samples.

How the data were processed

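Messenger RNA was measured in 56 mammary tumours of mice that carried the polyoma middle T antigen transgene (PyMT) under the mouse mammary tumour virus promoter. The mice came from crosses with 18 sublines of AKXD, a set of recombinant inbred mouse lines derived from the strains AKR/J and DBA/2J. Each tumour was hybridised to 2 single-colour Affymetrix arrays, MOE430A (array A) and MOE430B (array B). Apart from control probe sets and 100 others present on both, these hold different probe sets. Total RNA was extracted with Trizol and a silica column and labelled with biotin, per the labels' protocols. There were 3 tumours in 16 of the sublines and 4 in 2 of them, sublines 2 and 25. The labels call the tumours of a subline biological replicates and give each an animal number.

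The deposited values are log2 expression values made with RMA (robust multi-array average), per the submitters' processing notes. The version, the probe set definition and the genome build are not given in the sources used here. The values ran from 3.71 to 14.89 on array A and from 3.51 to 14.34 on array B. The 2 arrays were deposited as separate tables and were tested separately. All columns belonged to the 112 arrays of the series (columns of other series: 0). No counts or detection calls were used, so the number of arrays limits the precision.

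The deposited log2 values were used as given. The 64 control probe sets of each array were set aside, which left 22626 probe sets on array A and 22511 on array B. Gene symbols came from the platform annotation, brought up to date through the RefSeq gene table of assembly GRCm38.p6, which served for names and for which genes neighbour each other. On array A 20380 probe sets had 1 symbol, 691 had several and 1555 had none. On array B the numbers were 14673, 233 and 7605. No gene was named from a probe set with several symbols.

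Differences among the 18 sublines were tested with limma 3.58.1 in R 4.3.3, by the moderated F test of a model with 1 mean per subline (lmFit and eBayes, 38 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all probe sets of an array, and an adjusted p under 0.05 is called. In the same fit each subline was compared with the unweighted mean of the other sublines, adjusted within each comparison. The share of variance between sublines is given as the intraclass correlation.

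There were 23 gene lists, 12 of cell types and 11 of pathways or gene families, fixed with the tests and the rule for named genes before the data were examined. A list score is the mean over the list's genes of the log2 value minus the gene's mean, with 1 probe set per gene, the brightest. Scores were compared among sublines by a one-sided permutation test of the F statistic with 100000 resamples, and between 1 subline and all other tumours by a two-sided exact permutation test (Python 3.11.15, numpy 2.4.6). They were adjusted over all lists, or over all lists and sublines. Composition of the tumour sample was entered as the scores of 4 lists, adipocytes, T cells, B and plasma cells, and skeletal muscle.

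The rule for named genes took the first 20 genes by F test on array A and the first 8 on array B. For each subline it took the called gene with the largest difference in each direction whose tumours all lay on the same side of the mean of the others, given in full for the 5 sublines with most calls. Of each list it took up to 4 members with the smallest p, and all members of the list of proposed metastasis modifiers. The rule was applied with all arrays and again with the arrays that stood apart left out. Genes outside it are said to have been chosen after their values were seen.

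Each array was checked by its median Pearson correlation with the other arrays of its type and by its control probe sets. An alternative added after seeing the data left out arrays with a median correlation under 0.95, which kept 52 of 56 arrays A in 17 sublines and 53 of 56 arrays B in 18 sublines. Those arrays are called the kept arrays. Called probe sets were said to have 2 levels where the levels lay at least 5 pooled SDs apart with at least 5 tumours on each, a criterion set after seeing the data, since a stricter one tried first left no probe set on array B. A limit of 0.93, the kept arrays without tumour 1 of subline 21, and the kept arrays without sublines 2, 20, 24 and 27 were also added after seeing the data. The alternatives fixed beforehand were the replicate number as a block, leaving out the dimmer part of the probe sets, quantile normalization, median centring, array quality weights, a trended robust prior, composition scores or animal number as covariates, and leaving out each replicate in turn. For list scores they were other summaries of the members, the replicate block, array B members and leaving out replicates.

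The scripts were tested on simulated data, for limma independent normal noise with each probe set's mean and within-subline SD from the kept arrays. Probe sets were uncorrelated there and no array was poor. The calls of unchanged probe sets therefore do not give the rate of false calls on the real arrays. With 22626 probe sets of array A, a shift of 1 on the log2 scale in 3 tumours of a subline was called for 96% of 100 changed probe sets in the comparison of that subline and for 90% in the test among sublines, with 16 and 8 unchanged probe sets called. At a shift of 2 the shares were 100% and 98%. On array B, with 22511 probe sets, they were 99% and 96% at a shift of 1, and 100% and 98% at a shift of 2. The list score test among sublines called 2.5% of 40 scores without an effect. It called 97.5% where the means of all 18 sublines varied with an SD of 1 tumour SD, and 100% at 2 tumour SDs. This does not give the power for a shift in 1 subline.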

Results

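Expression was profiled in 56 PyMT-induced mammary tumours from crosses with 18 AKXD sublines, so that inherited differences in tumour gene expression could be compared across a fixed panel of genotypes. Each tumour was a separate animal by its label. No subline served as a control. P-values therefore describe how far sublines differ relative to the spread between tumours of a subline. No 2 arrays held identical values, and the most similar pair on array A, tumours 1 and 2 of subline 9, had a correlation of 0.996.

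Most arrays were closely alike, with a median correlation of 0.988 on both array types, but 4 arrays A and 3 arrays B stood apart. On array A tumour 3 of subline 23 had a median correlation of 0.222. Its Cre hybridisation control read 7.26, against 12.51 to 13.27 on the kept arrays, and its absent poly-A controls read 7.55, against at most 5.09. Its array B was ordinary, at 0.989. The array A correlations of tumours 2 and 1 of that subline were 0.918 and 0.948. Tumour 3 of subline 25 was low on both arrays, at 0.869 on A and 0.860 on B, and on array B tumour 3 of subline 11 and tumour 2 of subline 23 read 0.866 and 0.920. Tumour 1 of subline 23 had a 3' minus 5' signal of the Gapdh control of 1.23 on both arrays. The highest value on the kept arrays A was 0.19.

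**Figure D1:**
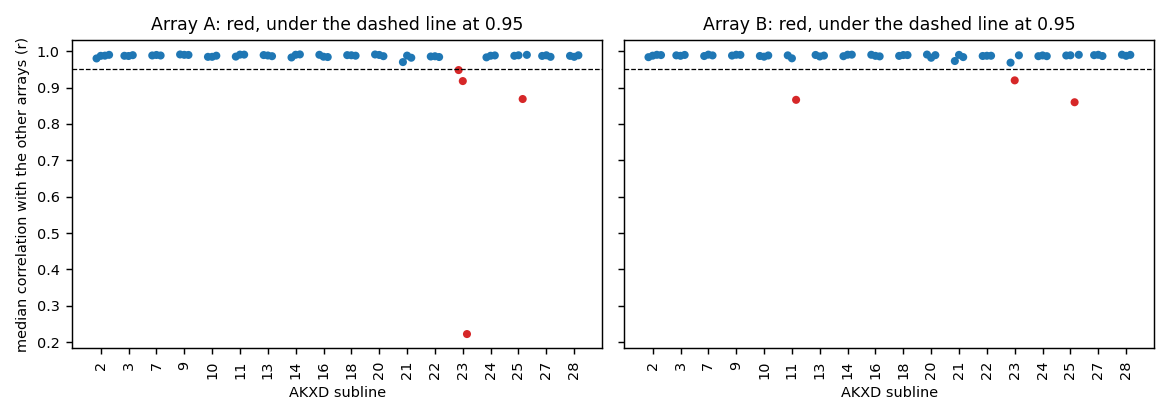
Median Pearson correlation (r) of each array with the other arrays of its type, by AKXD subline, for array A (left) and array B (right); 1 point is 1 tumour. The 4 red points on array A include tumour 3 of subline 23 at 0.222, and 3 red points on array B lie under the dashed line at 0.95.

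Which genes differed among sublines was tested first. The genes ranked first included Uqcr10, H2-D1, H2-Ea and Pdxdc1, and the values given are each of 1 probe set. Uqcr10, a subunit of mitochondrial complex III, ranked first and ran from 6.93 ± 0.09 on the log2 scale in subline 18 to 8.09 ± 0.06 in subline 24 (SD, n = 3 each, kept arrays; limma adjusted p = 2.16e-10). Another of its probe sets was called (adjusted p = 0.000618), and the brightest (mean 11.38) did not pass (adjusted p = 0.584). On 1 probe set of H2-D1, a heavy chain of class I of the major histocompatibility complex (MHC), the signal ran from 5.49 ± 0.28 in subline 24 to 10.33 ± 1.12 in subline 7, or 28.7-fold (adjusted p = 6.28e-06). On 3 other called probe sets of H2-D1 the levels were the opposite in 52 of 52 tumours, and the 2 brightest (means 12.76 and 12.44) did not pass (adjusted p = 0.759 and 0.709). H2-Ea, an MHC class II alpha chain, ran from 6.68 ± 0.12 in subline 21 to 9.85 ± 0.75 in subline 24 (adjusted p = 9.70e-05). Pdxdc1, a pyridoxal-dependent decarboxylase domain protein, read 4.47-fold higher in subline 27 than in subline 18 (adjusted p = 6.28e-06).

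With all arrays, 889 probe sets of 767 genes on array A were called among sublines, 3.93% of those tested (196 probe sets without replicate 3). With the kept arrays 393 probe sets of 314 genes were called, of which 143 were also among the 889. The 393 became 14, 92 and 34 without replicate 1, 2 and 3, which leaves most sublines with 2 tumours, and 4998 at a correlation limit of 0.93, which keeps tumour 1 of subline 23 in addition. Of the 20 genes ranked first with all arrays, Uqcr10, Pdxdc1, Kctd14, H2-D1, H2-Ea, Supt20, Metap1d and Sdc4 were also called with the kept arrays. The others were not: Usp7, a deubiquitinase, had an adjusted p of 3.36e-07 with all arrays and 0.470 with the kept arrays, Diaph1, a formin, had 3.61e-05 and 0.170, and Keap1, the sensor of the oxidative stress response, had 0.000586 and 0.214. The same loss was seen for Tex261, Coprs, Wbp1l, Slc3a2, Zcchc14, Igbp1, Usp5, Nr2c1 and Abcf1, whose kept adjusted p ran from 0.335 for Slc3a2 to 0.844 for Igbp1.

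With the kept arrays the 20 leading genes also held Suz12, Paip1, Pop4, Adi1, Mpdz, Kif5b, Vcp, Zfp277, Pfn1, AI506816, Hyou1, Map2k5, Mvb12b, Alg14 and Vps37c. Paip1, which binds the poly(A)-binding protein in translation, was highest in subline 3 at 6.30 ± 0.30 (n = 3; limma adjusted p = 8.37e-07). In 11 sublines its mean lay between 4.33 and 4.46, under the absent poly-A controls of the kept arrays (4.71 to 5.09), and its brighter probe set (mean 9.21) did not pass (adjusted p = 0.501). Kctd14, of the potassium channel tetramerisation domain family, was 5.01-fold higher in subline 21 than in subline 24. A brighter probe set of array A was also called (adjusted p = 3.06e-05; r = 0.995 between both over subline means), and its 2 probe sets on array B did not pass (adjusted p = 0.755 and 0.566). Adi1, an enzyme of the methionine salvage pathway, differed 2.19-fold between sublines 13 and 18, and Hyou1, a chaperone of the endoplasmic reticulum, 1.88-fold between sublines 25 and 10. Kif5b, a kinesin heavy chain, was 2.07-fold higher in subline 13 than in subline 22 on its brightest probe set. Its other probe sets did not pass (limma adjusted p = 0.233 to 0.928). Pfn1, the actin-binding protein profilin, was 1.58-fold higher in subline 21 than in subline 16. Mvb12b and Vps37c, subunits of the ESCRT-I sorting complex, each differed 1.83-fold between their extreme sublines on 1 probe set. The other probe sets of Mvb12b, among them the brightest (mean 10.82), did not pass (adjusted p = 0.585 to 0.769), and the other of Vps37c was called (adjusted p = 0.0439). Over the 393 called probe sets the median range of subline means was 0.71 on the log2 scale.

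**Figure D2:**
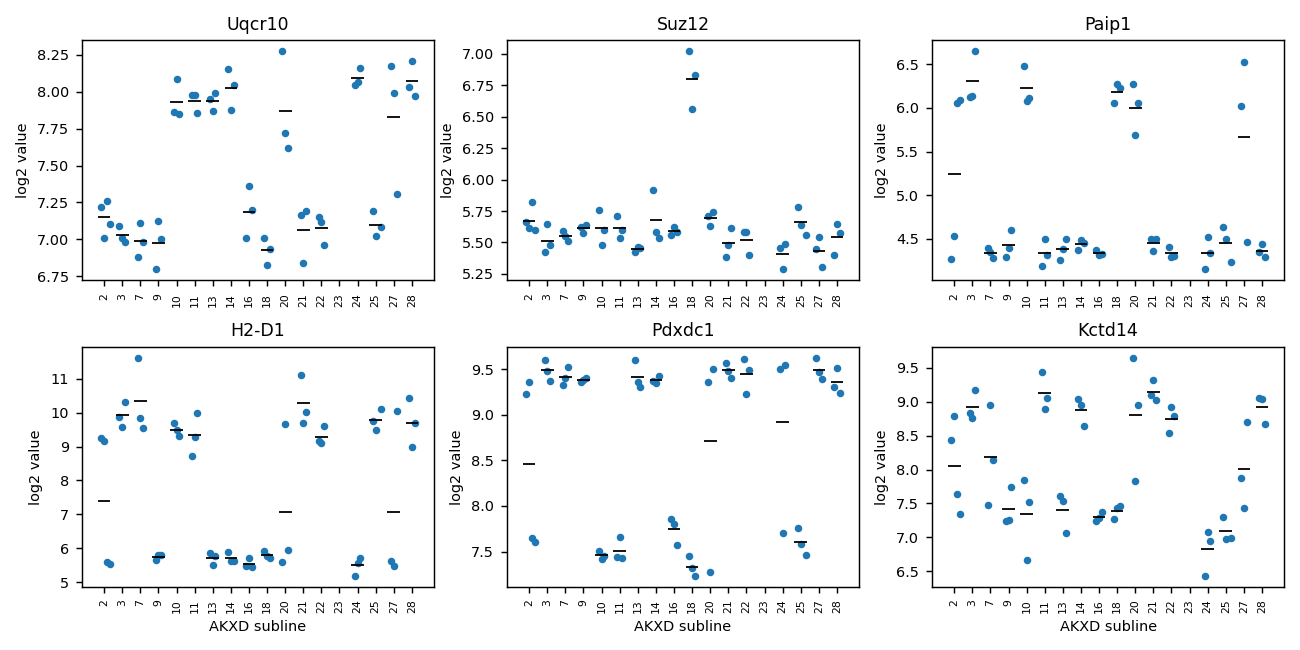
Log2 RMA values on array A of Uqcr10, Suz12, Paip1, H2-D1, Pdxdc1 and Kctd14 by AKXD subline, 1 probe set per gene, kept arrays only; points are tumours and bars are subline means. In Suz12 subline 18 stands alone at a mean of 6.80, and H2-D1 lies near 6 or near 10 in most tumours.

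Probe sets of 1 gene did not always move together. Suz12, a subunit of the Polycomb repressive complex, was higher in subline 18 by 1.24 ± 0.07 (log2, SE, n = 3) on 1 probe set and also called higher on another, which is too near the absent controls (mean 4.71) for a size. It differed by -0.91 ± 0.15 and -0.85 ± 0.14 on 2 others, each past the threshold. Pdxdc1 in subline 18 differed by -1.49 ± 0.28 on 1 probe set and by 0.56 ± 0.11 on another (limma adjusted p = 0.00914 and 0.0243). H2-D1 in subline 21 was higher by 2.58 ± 0.63 on the named probe set (adjusted p = 0.0168), and read -1.91 ± 0.63, -1.12 ± 0.43 and -1.51 ± 0.50 on the 3 probe sets with opposite levels, which did not pass in this comparison (adjusted p = 0.0786, 0.134 and 0.0803). Levels of Pdxdc1 on 2 probe sets were also opposite in 52 of 52 tumours. Of 43 genes named by rank among sublines, 38 had several probe sets, and in 14 of these at least 2 were called with the kept arrays and in 16 only 1 was. The direction of a difference in these genes thus belongs to the probe set named.

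On part of the 18 probe sets of array A with 2 levels, tumours of 1 subline fell on both levels, on 15 in subline 2, 16 in subline 20, 8 in subline 24, 10 in subline 27 and 4 in subline 7. On array B, of 7 such probe sets, these were 3, 1, 4, 5 and 2. Pdxdc1 read 9.23 and 9.36 in tumours 1 and 2 of subline 2 and 7.65 and 7.61 in tumours 3 and 4. H2-D1 read 9.25 and 9.18 in the first pair and 5.58 and 5.54 in the second. In subline 20, tumour 2 read 7.28 for Pdxdc1 and 9.67 for H2-D1, while tumours 1 and 3 read 9.36 and 9.50 for Pdxdc1 and 5.59 and 5.95 for H2-D1. In subline 27, H2-D1 read 10.06 in tumour 3 against 5.63 and 5.47 in the others. Paip1 and Mtmr9, the latter chosen with Cap1 after its values were seen, parted the same tumours of subline 2, and these 4 genes lie on different chromosomes in GRCm38.p6. Without sublines 2, 20, 24 and 27, 370 probe sets on array A and 138 on array B were called among the remaining sublines with the kept arrays.

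**Figure D3:**
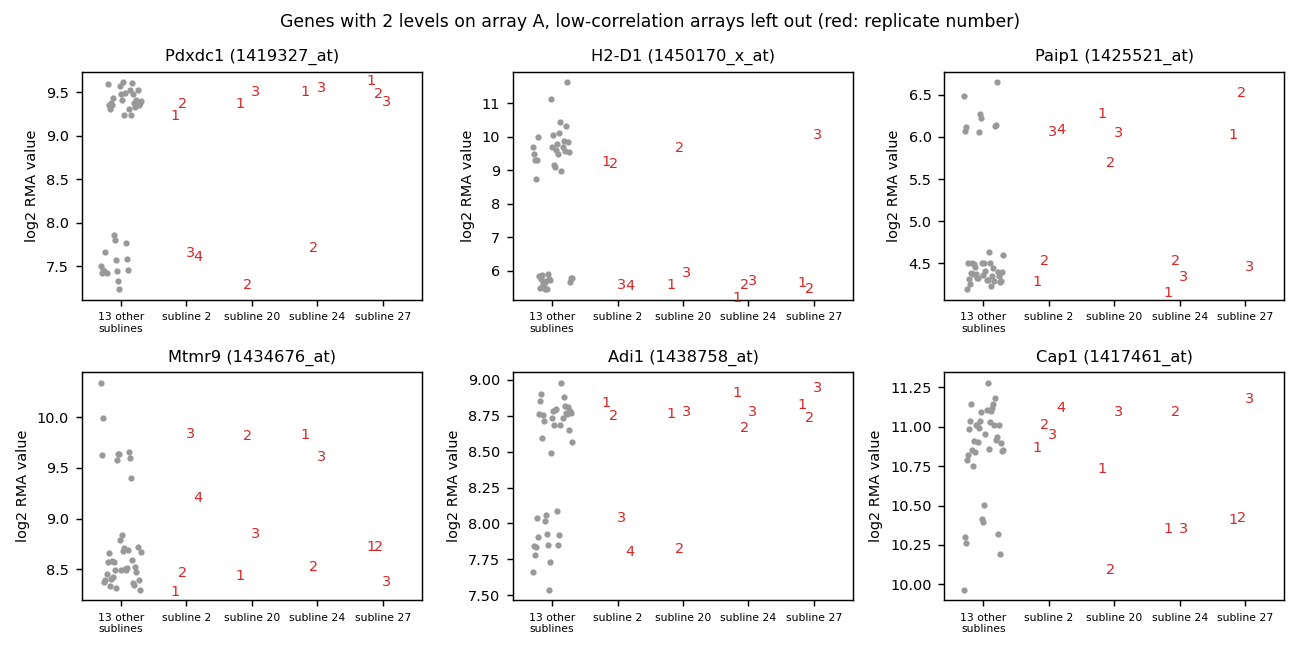
Log2 RMA values on array A of Pdxdc1, H2-D1, Paip1, Mtmr9, Adi1 and Cap1, kept arrays only: grey points are tumours of the other sublines, with no meaning in their horizontal order, and red digits are the replicate numbers of tumours in sublines 2, 20, 24 and 27. For Pdxdc1, tumours 3 and 4 of subline 2, tumour 2 of subline 20 and tumour 2 of subline 24 lie on the low level.

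Array B, which measures the same tumours with mostly other probe sets, gave fewer differences. Xaf1, an interferon-inducible partner of the apoptosis inhibitor XIAP, was 5.63-fold higher in subline 3, at 10.20 ± 0.51, than in subline 22, at 7.70 ± 0.11 (n = 3 each; limma adjusted p = 2.46e-05 with all arrays), while its other probe set did not pass (adjusted p = 0.458). Hspa13, of the HSP70 chaperone family, ran from 8.44 ± 0.22 in subline 11 to 10.10 ± 0.16 in subline 21 with all arrays (n = 3 each; adjusted p = 0.000182). Marchf3, a membrane ubiquitin ligase, was 3.61-fold higher in subline 21 than in subline 24 on 1 probe set, and its brightest did not pass (kept adjusted p = 0.580). Plb1, a phospholipase, was 2.82-fold higher in subline 16 than in subline 11 with the kept arrays. Paip1, measured by another probe set here, again had a high mean in subline 10 (5.90 ± 0.23) and was called (adjusted p = 2.46e-05), though a brighter one did not pass (adjusted p = 0.831). Also called were Tia1, an RNA-binding protein of stress granules, Ttc3 and Fbxw11, both of the ubiquitin system. The brightest probe set of each on either array did not pass (kept limma adjusted p = 0.430, 0.685 and 0.507). A probe set of Ttc3 on array A was called (kept adjusted p = 0.00491). The called Fbxw11 probe set is dim (mean 5.03), near the absent controls of the kept arrays B (at most 4.88). With all arrays 30 probe sets of 17 genes were called, and with the kept arrays 151 of 99 genes, all 30 among them. Without replicate 1, 2 and 3 the 30 became 0 by limma (910 at a raw p under 0.05), 5 and 53, and the 151 became 25, 29 and 255. Pisd-ps3, a phosphatidylserine decarboxylase pseudogene, joined the first 8 genes there, 2.39-fold higher in subline 22 than in subline 23.

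Each subline was then compared with the mean of the others. On array A with all arrays, subline 23 took 15669 of 15709 calls (6656 of 6815 without replicate 3), 8089 higher and 7580 lower, led by the transcription factors Rreb1 (2.16 ± 0.27 on the log2 scale, SE, n = 3; 1.22 without replicate 3) and Sox4 (-3.10 ± 0.42; -2.93 without replicate 3). With the dimmer probe sets left out it had 607 higher and 7043 lower. All 3 of its arrays A are below 0.95, so with the kept arrays the subline is not tested. Subline 21 had 36 probe sets higher and 0 lower by limma (873 and 346 at a raw p under 0.05), and 1, 51 and 5 calls without replicate 1, 2 and 3. Its leading gene was A2m, the protease inhibitor alpha-2-macroglobulin, 2.46 ± 0.43 higher and above the mean of the others in each of 3 tumours (adjusted p = 0.00684), though not past the threshold without replicate 1 or without replicate 3 (2.30 and 2.25). Subline 22 had 0 higher (438 at a raw p under 0.05) and 3 lower, led by Atrx, a chromatin remodeller, at -1.16 ± 0.21 (adjusted p = 0.0225), which did not pass without replicate 1 (-0.83) or without replicate 2 (-1.16). Without replicate 1, 2 and 3 these 3 calls became 5, 0 by limma (487 at a raw p under 0.05) and 149. Of the 3, Galnt7 (-0.98 ± 0.17) and Pcmtd1 (-0.93 ± 0.17) are named after their values were seen. Subline 27 had 1 call, Bpifa2, a parotid secretory protein. The other 14 sublines had 0 by limma, with 106 probe sets (subline 13) to 3581 (subline 25) at a raw p under 0.05.

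With the kept arrays 1764 calls were made in 12 sublines, most in subline 22 (217 higher, 579 lower) and subline 21 (545 higher, 224 lower). Without replicate 1, 2 and 3 the 1764 became 525, 1295 and 825, those of subline 22 became 151, 101 and 567, and those of subline 21 became 118, 1118 and 223. In subline 22, Ces1d, a carboxylesterase, was higher by 1.52 ± 0.41 and Scd2, a stearoyl-CoA desaturase, differed by -1.57 ± 0.28 (SE, n = 3; limma adjusted p = 0.0267 and 0.000651). The Ces1d probe set is dim (mean 5.27), near the absent controls of the kept arrays (at most 5.09). Neither it nor a brighter one (mean 6.98) was called among sublines (limma adjusted p = 0.418 and 0.485, kept arrays). In subline 21, H2-D1 led the higher genes, as above, and Mtm1, the phosphatase myotubularin, the lower ones at -0.92 ± 0.15 (adjusted p = 0.000805). A2m stood 2.45 ± 0.45 higher there, and Ptgs2, the inducible cyclooxygenase, named after its values were seen, 1.92 ± 0.20 higher (adjusted p = 1.99e-07). Without tumour 1 of subline 21, 205 probe sets were called in that subline in place of 769, and 113 were called both times.

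In subline 28, with 15 higher and 75 lower, Tspan8, a tetraspanin, was lower at -1.80 ± 0.43 in 3 of 3 tumours (log2, SE; limma adjusted p = 0.0467). Mucl1, a small mucin-like protein, led the higher genes through a single tumour, replicate 1, which read 10.49 against at most 4.66 in any other, under the absent controls. In subline 16, with 48 higher and 18 lower, Krt27, a hair follicle keratin, was higher by 1.23 ± 0.26 and Ghr, the growth hormone receptor, was lower at -0.69 ± 0.14 (adjusted p = 0.0228 for both). Tumour 3 carried the difference in Krt27, which was 0.24 without replicate 3. In subline 10, with 7 higher and 5 lower, Paip1 was called higher, at 6.22 ± 0.22 (SD), and Pdxdc1 was lower at -1.36 ± 0.28 (SE; adjusted p = 0.00438 and 0.0337). No size is given for Paip1, since most sublines lay under the absent controls.

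The remaining sublines had 11 calls or fewer with the kept arrays. Paip1 was also called higher in subline 18 (6.19 ± 0.11, SD, n = 3) and in subline 3, where Alg14, of the N-glycan pathway, was lower at -0.41 ± 0.08 (SE). Pdxdc1 led the lower genes of subline 18. Usp24, a deubiquitinase, was 0.80 ± 0.15 higher in subline 14 and Stx7, a syntaxin of endosomes, read -0.51 ± 0.09 there. Uqcr10 was higher in subline 24 by 0.65 ± 0.10 and Kctd14 lower at -1.35 ± 0.25, and Pitpnc1, a phosphatidylinositol transfer protein, was 0.54 ± 0.09 higher in subline 25 (limma adjusted p = 0.00508). Bpifa2 in subline 27 was higher by 3.52 ± 0.60, but tumour 3 read 13.12 and the next highest of all kept tumours 8.92, and it did not pass without replicate 3 or without replicate 1 (3.94), nor with all arrays (1.47 and 3.88). Of 22 differences named here for single sublines with the kept arrays, 6 were called without replicate 1, 10 without replicate 2 and 3 without replicate 3. Those of A2m in subline 21 and Atrx in subline 22 were called each time, and 9 were called in none of the 3. Subline 9 had 1 call, a probe set without a single gene symbol. Sublines 2, 7, 11, 13 and 20 had 0 by limma, with 2367, 1058, 1377, 677 and 658 probe sets at a raw p under 0.05. Tumours of sublines 2 and 20 fell on both levels of 15 and 16 of 18 probe sets with 2 levels. Their 0 calls therefore do not show that these tumours were like the others.

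**Figure D4:**
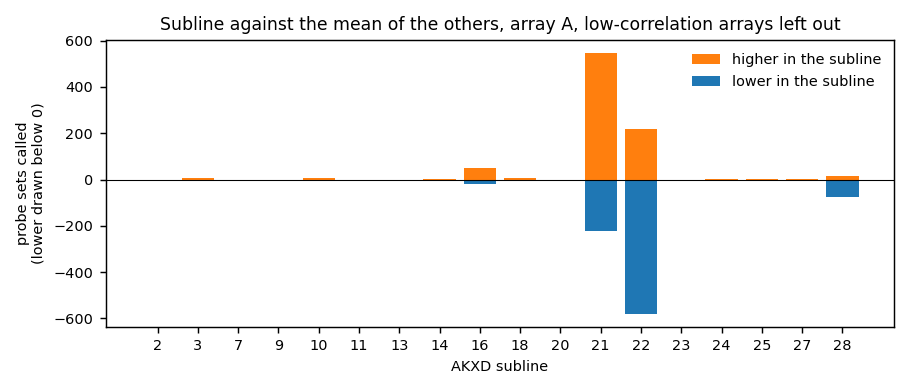
Probe sets called in the comparison of each AKXD subline with the mean of the others on array A, kept arrays; bars above 0 are higher and bars below 0 lower in the subline. Sublines 21 and 22 hold 769 and 796 of the 1764 calls, and subline 23 has no kept array.

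On array B subline 11 led with all arrays (717 higher, 1915 lower; 25 and 52 with the kept arrays). Subline 23 had 115 higher and 190 lower, and 269 and 555 with the kept arrays, where Kdm6b, a histone demethylase, was lower at -1.89 ± 0.35 (SE, n = 2; limma adjusted p = 0.00101). Pabpc4l led the higher genes there (adjusted p = 0.000229), on a probe set at the level of the absent controls (mean 4.61), so no size is given. Without replicate 1, 2 and 3 the subline had 4, 425 and 2566 calls with the kept arrays. Tumour 1, of the 2 left there, is that with the high Gapdh 3' signal. Subline 21 had 41 higher with all arrays and 161 higher and 21 lower with the kept arrays, led by Col25a1, a membrane collagen, at 1.98 ± 0.43 with all arrays (adjusted p = 0.0345). With quantile normalization again, the calls over all sublines of array B were 1372 higher and 1062 lower, against 881 and 2105.

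Gene lists asked whether the cell make-up or the programmes of the tumours differed among sublines. Single members differed while the scores of whole lists mostly did not. Each member was counted by its brightest probe set, so a call on another probe set of the gene does not enter the counts. Muc1, a luminal mucin, was 2.74-fold higher in subline 9, at 10.51 ± 0.13, than in subline 10, at 9.06 ± 0.42 (SD, n = 3 each; limma adjusted p = 0.00481 with all arrays, 0.00315 with the kept arrays). Ccna2, cyclin A2, ran from 10.11 ± 0.25 in subline 22 to 10.94 ± 0.04 in subline 28, and Pdk1, a kinase that restrains pyruvate dehydrogenase, from 8.47 ± 0.11 in subline 14 to 9.40 ± 0.13 in subline 3 (kept adjusted p = 0.0392 and 0.00578). On the kept arrays Ccna2 was not called without replicate 1, 2 or 3, and Muc1 and Pdk1 were not without replicate 1 or 3. Of 23 list scores on array A, 0 were called among sublines by the permutation test with all arrays, and 2 had a raw p under 0.05, the keratinocyte list (p = 0.0251) and the list of genes known to differ among inbred strains (p = 0.0389). Of 414 pairs of a list and a subline, 0 were called by the exact permutation test, 25 had a raw p under 0.05 and the smallest adjusted p was 0.307. With the replicate number as a block the keratinocyte list was called (permutation adjusted p = 0.0481).

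Among cell types on array A, the luminal list had 1 called member of 13 with all arrays (Muc1), also 1 adjusted over the list alone, and Cldn3, Elf5 and Krt18 did not pass (kept adjusted p = 0.167, 0.463 and 0.531). The Schwann cell list (5 members, among them Cnp, Sox10, Mbp and Pmp22) had 0 members called over all genes by limma (2 with the kept arrays at a raw p under 0.05) and 1 adjusted over the list alone, and its score was called with the kept arrays only (F = 3.69, intraclass correlation 0.468, permutation adjusted p = 0.0152; 0.0644 and 0.543 with all arrays). With the kept arrays without replicate 1, 2 or 3 no list score was called by the permutation test. The Schwann cell score was lowest in subline 28, 0.21 below the others (a difference of -0.21, exact permutation p = 0.00086, adjusted p = 0.336, 3 of 3 tumours). The T cell list had 0 of 11 called over all genes by limma (1 at a raw p under 0.05) and 1 adjusted over the list alone with all arrays, and 0 with the kept arrays. Keratinocyte markers had 0 of 8 (3 at a raw p under 0.05), and 1 adjusted over the list alone with the kept arrays. Markers of basal cells (10), adipocytes (9), B and plasma cells (10), macrophages (12), neutrophils (8), endothelium (12), skeletal muscle (12) and red blood cells (4) had 0 called members by limma, over all genes and adjusted over the list alone, with all arrays and with the kept arrays. At a raw p under 0.05 with all arrays, macrophages, endothelium and red blood cells had 1 each and the other 5 lists 0. Adipocyte and muscle genes varied widely between tumours of a subline: Adipoq averaged 10.43 ± 1.23 in subline 22 and 7.21 ± 0.77 in subline 21 (adjusted p = 0.699), and Tnnt3 10.38 ± 1.44 and 7.58 ± 0.78 (adjusted p = 0.810).

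Among pathways, immediate early and heat shock genes had 1 called member of 14 with all arrays, Junb (limma adjusted p = 0.00855), and 4 adjusted over the list alone, but 0 and 0 with the kept arrays (3 at a raw p under 0.05). Cell cycle genes had 0 of 19 with all arrays (4 at a raw p under 0.05) and with the kept arrays 1, Ccna2, with 2 adjusted over the list alone. Hypoxia genes had 0 of 14 (6 at a raw p under 0.05), and with the kept arrays 1, Pdk1, and 1 adjusted over the list alone. The MHC list had 0 of 15 (1 at a raw p under 0.05), and with the kept arrays 1, H2-Ea by its brightest probe set, 1.71-fold higher in subline 9 than in subline 22, and 1 adjusted over the list alone, while Tap1, Tap2 and H2-K1 did not pass. Dimmer probe sets of H2-D1 and H2-Ea were called both ways, as given above. Milk protein genes had 0 of 12 called over all genes (3 at a raw p under 0.05) and 1 adjusted over the list alone with all arrays, and Csn2, beta-casein, averaged 13.09 ± 1.31 in subline 16 and 9.15 ± 2.80 in subline 14 (n = 3 each; adjusted p = 0.332). Matrix genes had 0 of 23 (1 at a raw p under 0.05), and 1 adjusted over the list alone with the kept arrays. Other probe sets of the member Timp2 were called with the kept arrays. On array B, with the kept arrays, 1 list member in all was called over all genes, the matrix gene Thbs2, a thrombospondin (adjusted p = 0.0451). Adjusted over the list alone there, 2 of 3 basal genes, 3 of 6 genes known to differ among inbred strains, 2 of 6 cell cycle genes, 1 of 3 muscle genes and 1 of 7 matrix genes were called. With all arrays B 0 members were called over all genes by limma, with at most 1 of a list at a raw p under 0.05, and 1 basal gene adjusted over the list alone. Interferon genes had 0 of 14 both ways (3 at a raw p under 0.05). Irf7 averaged 10.61 ± 0.98 in subline 7 and 8.78 ± 0.34 in subline 14 (n = 3 each; adjusted p = 0.331), and the interferon score of subline 14 differed from the others by -0.80 (exact permutation p = 0.00653, adjusted p = 0.307, 3 of 3 tumours). Fatty acid and sterol genes had 0 of 13 both ways (2 at a raw p under 0.05). A dimmer probe set of the member Scd2 was called both ways (limma adjusted p = 0.00727 with all arrays and 0.0418 with the kept arrays).

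Genes known to differ among inbred strains had 0 of 18 called over all genes by limma (5 with the kept arrays at a raw p under 0.05), and 3 adjusted over the list alone with the kept arrays. Glo1, glyoxalase 1, averaged 11.91 ± 0.12 in subline 10 and 11.24 ± 0.12 in subline 22 (n = 3 each; adjusted p = 0.0946 among sublines). The X inactivation and Y-linked list had 0 of 4 (1 at a raw p under 0.05), and 1 adjusted over the list alone with the kept arrays. Xist, the RNA of the inactive X, averaged 11.24 ± 0.37 in its lowest subline, 14, and Kdm5d, Uty and Eif2s3y had kept subline means of at most 6.49, 5.23 and 4.29.

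AKXD crosses with PyMT mice have been used to search for inherited modifiers of metastasis, and none of the proposed modifiers measured here was called with all arrays or with the kept arrays. Of 6 on array A and 3 on array B, 0 passed by limma over all genes or adjusted over the list alone, with all arrays or with the kept arrays (1 on array A at a raw p under 0.05 with all arrays). Among 24 or 26 alternative settings for each, Ndn, Sipa1 and the array B probe sets of Cnot2 and Tpx2 were called in 2. Rrp1b and Cadm1 were called in 1. Tpx2, a spindle assembly factor, averaged 9.24 ± 0.13 in subline 28 and 8.64 ± 0.34 in subline 20 (SD, n = 3 each; kept adjusted p = 0.370). Sipa1, a Rap GTPase-activating protein, averaged 8.30 ± 0.21 in subline 24 and 7.93 ± 0.09 in subline 16 (adjusted p = 0.417), and Rrp1b, a nucleolar protein, 8.80 ± 0.24 in subline 28 and 8.42 ± 0.05 in subline 24 (adjusted p = 0.624). Ndn, Cnot2 and Cadm1 had adjusted p of 0.480, 0.944 and 0.894. On array B, Cnot2, Tpx2 and Arhgap25 had 0.741, 0.799 and 0.908. The range between the extreme subline means was 0.59 on the log2 scale for Tpx2 on array A, the widest of the 9.

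**Figure D5:**
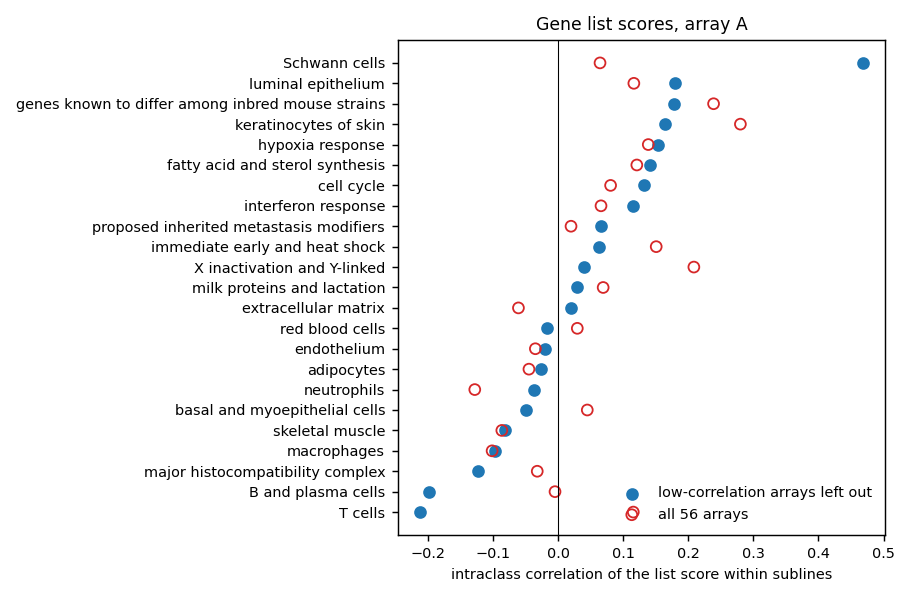
Intraclass correlation of each of 23 gene list scores within AKXD sublines on array A, with the kept arrays (filled) and all 56 arrays (open). The Schwann cell list stands at 0.468 with the kept arrays and 0.0644 with all arrays.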

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

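The tests of a failed array, of degraded RNA, of tumour 1 of subline 21, of composition in subline 21, of cartilage genes, of the largest group in each split and of the arrays B of tumours closer to another subline were chosen only after the result was seen, as were the limit for the kept arrays and the criterion for 2 levels.

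Tumour 3 of subline 25 lay far from the other 3 tumours of its subline in 46 of the 53 groups of 4 tumours, among 396 checked, in which 1 tumour stood apart by the size of its gap to the nearest other. Chance alone gives about 1 in 20 groups. This tumour has median correlations of 0.869 on array A and 0.860 on array B. On the log2 scale it was below the others of array A for the actin regulators Pfn1 and Diaph1, for cell cycle, antigen presentation and luminal genes among others: Diaph1 8.71, Keap1 7.49, Pop4 7.45, Kif5b 9.44, Pfn1 11.66, AI506816 8.43, Vps37c 7.00, Tap1 7.69, Muc1 9.33, Cldn3 11.79, Pdk1 8.51, Ccna2 9.59, Cdc20 9.26, Glo1 10.07, Sox10 11.59, Mbp 8.28, Ier2 8.87, Esam 8.31, Dnajb1 8.45, Plk1 8.54, Mcm5 7.79, B2m 11.97 and Serpinh1 9.32. It was above them, mostly in genes that are dim in the other tumours, such as lymphocyte and neutrophil markers: Usp7 7.24, Suz12 7.00, Kdm5d 8.31, Cd8a 6.96, Cd5 7.91, Olah 6.82, Egfl7 10.08, Pparg 7.78, S100a9 7.45, Pgr 7.06, Camp 9.06, Krt17 7.99, Cr2 7.44, Pax5 7.54 and Lep 6.98. On array B it was below them for Plb1 7.80, Fbxw11 4.86, Pisd-ps3 6.60 and Tpx2 7.70. Its scores were -0.45 for the luminal epithelium list, -0.80 for the cell cycle list, -1.03 for the immediate early and heat shock list and 0.83 for the X inactivation and Y-linked list. Its Cre hybridisation control read 11.73 on array A and 11.35 on array B, against at least 12.51 and 12.54 on the kept arrays. Its absent poly-A controls read 5.77 and 5.28, against at most 5.09 and 4.88. Dim genes mostly read high and bright genes low across unrelated cell types, and no biological explanation was tested. The values listed are therefore not taken as traits of the tumour.

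The other 7 came from sublines 2 and 25. In subline 2, tumour 1 read 7.10 for Abcf1 (others at most 6.78), 6.82 for Myo5a (others at least 6.96) and 7.70 for the neutrophil granule gene Camp (others at most 6.67). Tumour 3 read 7.61 for the T cell receptor subunit Cd3d (others at most 7.41), and tumour 2 had a hypoxia score of 0.79 (others at most -0.07). In subline 25, tumour 4 read 7.08 for the endothelial receptor Tek (others at most 6.72), and tumour 1 had a milk protein score of 0.52 (others at most 0.01).

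Subline 23 had 15669 calls on array A with all arrays, among them Sox4 and Rreb1. A property of its tumours as the whole cause is argued against by array B, which holds the same tumours, since of 100 probe sets present on both arrays 85 were called in the subline on array A and 2 on array B (8 with the kept arrays B). For part of the calls it stays open. With the kept arrays B the subline had 269 higher and 555 lower, the most of any subline there. Those calls rest on tumours 1 and 3, and tumour 1 has a 3' minus 5' Gapdh signal of 1.23 on array B as well. They cannot tell a property of the subline from degraded RNA. A failed array in tumour 3 is a candidate explanation, since its Cre control read 7.26 against 12.51 to 13.27 on the kept arrays. Without replicate 3 of every subline 6656 calls were made in the subline, and for these degraded RNA in tumour 1 may contribute, with a 3' minus 5' Gapdh signal of 1.23 against at most 0.19 on the kept arrays A. The group of subline 23 had as many calls in 1 of 100 splits (highest other 13174), but as the subline was picked for its calls the largest group of each split is the fairer comparison: it was as large in 3 of 100 (highest other 16354, median 12202), and splits of this size point to a structure of the samples, so chance is not called excluded.

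Probe sets with 2 levels, several of them of the same gene, among them those of Pdxdc1, H2-D1, Paip1, Mtmr9, Adi1 and Uqcr10, put tumours of 1 subline on both levels in 59 pairs of a probe set and a subline on array A, 41 of them in sublines 2, 20 and 27 and 49 with subline 24. An exchange of arrays of 1 type is argued against for the 10 tumours closer to another subline on array A, each of which had its own array B as the best match for its array A (r = 0.550 to 0.921), and 6 of them were closer to another subline on array B as well (tumours 1 and 2 of subline 2, tumour 2 of sublines 7, 20 and 24, and tumour 3 of subline 27). Tumour 2 of subline 20 was closest to subline 10 on both arrays (r = 0.697 on array A over 393 called probe sets, against -0.530 with its own subline), and tumour 3 of subline 27 to subline 22 (0.657 against -0.271). For 3 of the 6 the closest subline differed between arrays. Of these, tumour 2 of subline 24 was closest on array B to subline 23, which has no kept array A, so the arrays could not agree. Tumour 2 of subline 7 was nearly as close to its own subline on array A (0.511 against 0.538). Tumours that do not share the genotype of their label may explain these placements. On array B 9 of 19 pairs lay in sublines 2, 20 and 27 (13 with subline 24), where an even share would be 3.17. This is below the share asked for beforehand. A subline that still segregates would give an excess too, so this count cannot tell the 2 apart. Segregation at these genes alone is argued against for tumour 2 of subline 20 and tumour 3 of subline 27. Over 151 called probe sets of array B, the former again matched subline 10 (0.688 against 0.335 with its own subline). The latter again matched subline 22 (0.657 against -0.137). For the other tumours segregation at these genes stays open, and wider segregation was not tested for any. A tumour of the wrong subline or from outside the panel also stays open.

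In subline 21, with 769 calls on the kept arrays, tumour 1 held extreme values: Olig1, a glial transcription factor, read 11.89 (next 9.31), Cnmd, a cartilage protein, 11.83 (next 9.15), the cartilage collagen Col2a1 12.19 (next 9.60) and the water channel Aqp4 9.67 (next 5.50), all chosen after their values were seen. That tumour alone may explain most calls, since 113 of 769 were called without it, though 1 tumour fewer also lowers the power. Composition of the sample could also contribute, as 327 of 769 were still called with the 4 composition scores. Cartilage-type tissue cannot be told apart from other sources: the tumour ranked first in the list score (0.86, next 0.37), and Col9a1, Col9a3, Col11a1, Col11a2 and Hapln1 stood over 2 SD above the other tumours, 5 of 12 members, but Acan, Matn1, Matn3, Epyc, Col9a2, Sox9 and Chad did not (Sox9 9.29 against a mean of 9.52). A property of the subline stays open, and A2m was still 2.23 higher there with the kept arrays without tumour 1, past the threshold by limma.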

How the results depend on the processing

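The settings that leave out low-correlation arrays, sublines or tumour 1 of subline 21 were chosen only after the result was seen. Every count is of probe sets past an adjusted p under 0.05 by limma, in the order among sublines on array A, all single sublines together on array A, subline 21, subline 22, subline 23, subline 27 and among sublines on array B where all are given. Arrays carry no counts, so signal over background was judged only from the absent poly-A controls, and the number of tumours limits what can be called. Replicate numbers do not pair tumours: of 460 pairs with the same number on array A 139 had a residual correlation over 0.1, the median was 0.00134, and on array B the values were 171 and 0.0205. The cause was not tested for the counts that moved, except where a setting tests fewer probe sets or tumours.

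With all arrays, for probe sets differing among the 18 sublines, array A, those among sublines on array B (probe sets differing among the 18 sublines, array B) and those in single sublines, the replicate block, median centring and the trended prior moved none of these counts by over 1.5 times. With the dimmer probe sets left out, the single sublines together gave 7660, subline 21 gave 5, subline 23 gave 7650 (607 higher and 7043 lower, against 8089 and 7580) and subline 27 gave 0 (123 at a raw p under 0.05). Quantile normalization again gave 225 among sublines on array A and 7 in subline 22. Array weights gave 17423 among sublines on array A, 35940 over single sublines, 21, 2833 and 9968 in sublines 21, 22 and 27, and 6903 on array B; the cause was not tested. Composition scores gave 389, 8840, 18 in subline 21, 0 in subline 22 (1030 at a raw p under 0.05), 8815 in subline 23 and 2 in subline 27. Animal number gave 537 among sublines on array A. Leaving out 1 replicate number in turn gave 196 (replicate 3) to 1011 (replicate 2) among sublines on array A, 6815 to 16703 over single sublines, 1 to 51 in subline 21, 0 (without replicate 2, 487 at a raw p under 0.05) to 149 in subline 22, 6656 to 16572 in subline 23, 0 (without replicate 1, 88 at a raw p under 0.05) to 3 in subline 27, and 0 (without replicate 1, 910 at a raw p under 0.05) to 53 (without replicate 3) on array B. The difference of Mucl1 in subline 28, 2.02 on the log2 scale, ranged from -0.022 (without replicate 1) to 3.10 (without replicate 3), since replicate 1 alone carried it and the others lie at background.

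Leaving out the low-correlation arrays gave 393 probe sets differing among the 18 sublines, array A, 1764 over single sublines, 769 in subline 21, 796 in subline 22, 2 in subline 27 and 151 probe sets differing among the 18 sublines, array B. At the limit 0.93 the counts were 4998, 10330, 619, 703, 8797 in subline 23, 7 in subline 27 and 151 on array B, so the array A count among sublines depends on tumour 1 of subline 23, the 1 array that this limit keeps in addition. Subline 23 is then that tumour alone, with its high Gapdh 3' signal, assumed to vary like the other groups, so its 8797 calls say nothing of the subline. With the kept arrays, the replicate block gave 403, 1772, 774, 809 and 125 on array B. The dimmer probe sets left out gave 377, 1549, 758, 599 and 156. Array weights gave 9234 among sublines on array A, 4 in subline 21, 2536 in subline 22, 7740 in subline 27 and 4798 on array B. The trended prior gave 367, 1693, 750, 758, 2 in subline 27 and 111. Composition scores gave 313, 1130, 399, 459, 5 in subline 27 and 120. Animal number gave 358, 1464, 611, 725 and 135. Without replicate 1 the counts were 14, 525, 118 and 151, without replicate 2 they were 92, 1295, 1118 and 101, without replicate 3 they were 34, 825, 223, 567, 23 in subline 27 and 255 on array B, and without replicate 4 they were 389, 1676, 697, 771 and 116 on array B. Leaving out replicate 1, 2 or 3 leaves most sublines with 2 tumours, and on array B it leaves subline 11 or 23 with 1, assumed to vary like the others. Without tumour 1 of subline 21 they were 401, 1302, 205, 876, 2 in subline 27 and 176, and without sublines 2, 20, 24 and 27 they were 370, 1998, 661, 968 and 138. In each case the cause was not tested beyond the fewer tumours or probe sets.

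The number of list scores called among sublines was 1 with the replicate block (keratinocytes), 1 with the kept arrays (Schwann cells) and 1 with the kept arrays without replicate 4 (Schwann cells), and 0 by the permutation test in the other settings (0 to 4 at a raw p under 0.05). For the named genes the counts that follow are set against the call from all arrays. Among sublines, with all arrays 1222 of 1341 values lay on the same side of the threshold as that call, 17 no longer passed and 102 newly passed, and with the kept arrays these were 1266 of 1516, 93 and 157. In the settings that leave out replicates or a tumour they were 1376 of 1575, 156 and 43. For genes named in 1 subline they were 161 of 179, 3 and 15 with all arrays, 56 of 185, 1 and 128 with the kept arrays, and 147 of 206, 8 and 50 where replicates or a tumour were left out, with 1 reversed (Mucl1). Many of these genes were named because they passed with the kept arrays, so that they newly passed was fixed by that choice, and a kept call lost without a replicate can count as the same side. Set against the call from the kept arrays, of 22 named differences in 1 subline 6, 10 and 3 were called without replicate 1, 2 and 3, of 27 named probe sets among sublines on array A 7, 24 and 12, and of 9 on array B 2, 7 and 8.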

Other observations

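The test of composition over all differing probe sets and the use of the kept arrays were chosen only after the result was seen, as were the comparison of genes with at least 2 called probe sets and the splits compared by their largest count in a subline.

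Some genes stood far higher in 1 tumour than in any other. Bpifa2, a parotid secretory protein, read 13.12 on the log2 scale in tumour 3 of subline 27, next 8.92, with a median of 5.39 over 52 tumours. Mucl1 read 10.49 in tumour 1 of subline 28, next 4.66, and Smgc, a submandibular gland protein measured on array B, read 6.09 in the same tumour, next 4.20. In tumour 1 of subline 21, Ecrg4 read 13.43 on array A and 12.84 on array B, next 11.38 and 10.87, Nptx1, a neuronal pentraxin, read 10.55, next 7.17, S100b 9.58, next 7.23, Comp, a cartilage matrix protein, 11.64, next 9.28, and Trpm3, an ion channel on array B, 8.61, next 6.03. These genes were chosen after their values were seen.

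Neighbouring genes moved together among sublines. Vcp, an ATPase, and Pigo, of the glycosylphosphatidylinositol pathway, had an absolute correlation of subline means of 0.917 across sublines of the kept arrays, and Metap1d with Pdk1 and Ttc3 with Pigp had higher ones. Over 58 pairs of called genes within 20 genes of each other the median was 0.491, against 0.248 when positions were shuffled and at most 0.356 in 1000 shuffles. Local inherited variation may therefore underlie part of the differences, as a hypothesis, and genotypes are not given in the sources used here. The correlations are over sublines that include sublines 2, 20, 24 and 27, whose tumours fell on both levels of several probe sets.

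Probe sets of the same gene were compared to ask whether 1 probe set alone changed, as a variant under its probes or an exon could cause. With 1 pair per gene, among the brighter probe sets of array A, of 125 genes with a called probe set and another one, 61.6% had a correlation over 0.5 between both (95% exact interval 52.5% to 70.2%), against 53.7% of genes with no called probe set, which cannot be told apart. Pairs that moved apart, with a correlation under -0.5, made up 1.6% (Pdxdc1 and Alg14) against 0.842%, which decides nothing, as these pairs left out dim probe sets and further probe sets of a gene. Among 33 genes with at least 2 called probe sets of any brightness, a comparison made after the values were seen, 3 had a pair under -0.5: H2-D1, Pdxdc1 and Suz12. For H2-D1 and Pdxdc1 the correlation of such a pair reached -0.983 and -0.967. A change in transcript level read alike by all probe sets of a gene cannot give opposite differences. A variant under the probes, which needs no change in level, or a change of exons or transcripts may underlie them. Neither was tested further.

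With the adipocyte, T cell, B and plasma cell and muscle scores as covariates, 254 of the 393 differing probe sets were still called. These scores thus do not account for those calls, but this cannot decide on composition of the tumour sample as a whole. Members of these lists hardly differed among sublines on the kept arrays (median intraclass correlation -0.0095, -0.155, -0.0974 and -0.0817). Other cell types were not entered as covariates, and composition could still account for part of the differences.

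Other splits of the same tumours into groups of the same sizes were fitted 100 times, the real one included. Among sublines on array A, chance can be excluded with all arrays (889 probe sets, 1 of 100 splits as large, highest other 363) and with the kept arrays (393, 1 of 100, highest other 26). With all arrays this does not separate subline differences from array quality, since all arrays A of subline 23 had a low correlation. Of the 889, 143 were also called with the kept arrays. On array B chance can be excluded with the kept arrays (151, 1 of 100, highest other 12) and not with all arrays (30, 7 of 100, highest other 5528). For the comparisons of 1 subline with the others, summed over sublines, it cannot be excluded with all arrays (15709, 9 of 100, highest other 21649) or with the kept arrays (1764, 6 of 100, highest other 4843). With the kept arrays as many calls were made in the group of subline 22, with Scd2 and Ces1d, in 1 of 100 splits (796, highest other 258), and in that of subline 21, with H2-D1 and Mtm1, in 4 of 100 (769, highest other 2020). Both were picked for their calls, and some group of a split had at least 796 calls in 13 of 100 splits (highest other 4757), so chance cannot be excluded for either count. It cannot be excluded for subline 27 (2, 13 of 100, highest other 353). With all arrays it cannot be excluded for subline 21 (36, 12 of 100, highest other 12867), subline 22 (3, 10 of 100, highest other 12871) or subline 27 (1, 19 of 100, highest other 12807). Splits that call several times the real count point to a structure of the samples. Arrays with low correlation are not the whole of it, as such splits also arose with the kept arrays (4843 against 1764). Its source was not tested.

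The arrays of a tumour were matched across array types by 100 probe sets present on both. Of 56 tumours 52 had their own array B as the best match for their array A, and of 51 tumours kept on both arrays 50 did.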
